A study of Mus musculus with 8 samples.

How the data were processed

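The samples were primary vascular smooth muscle cells from the carotid artery of male mice on a C57bl6 background that lack PMCA4, the plasma membrane calcium pump encoded by Atp2b4. Per the labels, 1 population was left as knockout cells, and the other was electroporated with cDNA of the splice form PMCA4a; the latter is called rescued here. Both were synchronised by serum, stimulated with serum and the growth factor PDGF-BB, and harvested in late G1/S. Total RNA was amplified into biotin-labelled cRNA for an Illumina bead array with 1 colour. There were 4 arrays per group and 8 arrays in all, grouped by the genotype in their labels. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. No array of knockout cells electroporated without PMCA4a was analysed here, so electroporation and PMCA4a differ together between the groups.

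The authors deposited 25697 probes with an intensity per array on a linear scale that was not normalized, per the file headers. Beside each intensity the deposited table gives a detection p-value. A second deposited table holds log2 values of the same probes, and its processing is not given in the sources used here. Set against the log2 values computed here, each of its columns had a correlation of 1 across probes and differed by at most 0.0266, with column medians from 5.17 to 5.18, so its scale and direction were those used here and its probes were not centred. The software that made either table is not given in the sources used here. The files give no slide or scan date, so no array batch could be tested.

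Intensities were background-corrected with the negative-control distribution inferred from the detection p-values and quantile-normalized with neqc in limma 3.58.1 under R 4.3.3, with an offset of 16 and a log2 scale. Probes detected at p under 0.05 on at least 4 of the 8 arrays were kept, which left 12658 probes. Differences are rescued minus knockout, fitted per probe with lmFit and eBayes. P-values were adjusted by Benjamini-Hochberg over all kept probes, with a threshold of 0.05. Means are of normalized log2 intensities, with the SD over 4 arrays. Normalization sets the arrays to a common distribution, so a shift of most transcripts together would be removed. For array data the number of arrays limits the precision. The brightest signals, 61011 to 65109 per array, lie near the limit of a scanner, where differences are compressed.

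Where a probe was not detected on any array of the dimmer group, the difference is given as at least N-fold. The bound sets the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the lowest level among detected probes and the probe's own level. It holds on the background-corrected scale; without background correction, differences of dim probes are smaller. Of all probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 had none. Of the named probes, 23962 matched a RefSeq gene table of assembly GRCm38.p6 by gene identifier. That table was used for symbols and chromosome membership, and no coordinates are given because the files name no build. A gene is represented by its kept probe with the highest mean over the 8 arrays, giving 8633 genes. Of 2323 genes with more than 1 kept probe, 10 had probes past the threshold in opposite directions.

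Before the data were examined, 24 pathway lists and 8 cell type lists were fixed, together with the main settings, the alternatives and the rule for named genes. The rule takes the PMCA pump genes; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap; for each list up to 4 members with the smallest p; and Rgs16, which the study followed up on these samples. Genes outside the rule are said to be chosen later. The 27 lists with at least 5 measured genes were tested with camera in limma, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Beside it stand camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance 1 way and does not compare them with other genes. Single measures between groups were compared by exact permutation tests, two-sided. Alternatives were other background corrections and normalizations, other detection filters, other variance models and array weights, the replicate number as a block, the deposited log2 values, the average of a gene's probes, other thresholds, and each array left out in turn.

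The procedure was tested on simulated data for this comparison, with 12658 probes. It recovered 72% of 100 probes changed by 1.5-fold and 92% of 100 changed by 2-fold, with 6 false calls. In a simulation of the lists over 8633 genes the shifted list was called and 0 of the others were. Both simulations drew genes independently and changed few of them. In the data 38.8% of probes passed, and estimated correlations within lists reached 0.37 for G2/M and 0.43 for interferon genes. The simulations therefore do not test the list calls under such correlation. Figures were drawn with matplotlib 3.10.9.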

Results

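Gene expression was measured on 8 bead arrays, 4 of PMCA4 knockout carotid smooth muscle cells and 4 of the same kind of cells electroporated with PMCA4a cDNA, all harvested in late G1/S after stimulation with serum and PDGF-BB. The design compares these 2 synchronised populations, and so asks which transcripts differ between them. Of 25697 probes, 12738 ± 99.8 (SD, n = 4) were detected on the rescued arrays and 12348 ± 98.4 (n = 4) on the knockout arrays. This difference had an exact permutation p of 0.0286, the smallest that 4 against 4 can give. Median signals did not separate, at 116 ± 1.49 against 115 ± 4.45 units of intensity (n = 4 each, exact permutation p = 0.657).

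The pump gene itself did not separate the groups. Atp2b4 (probe ILMN_1217742) had a log2 intensity of 5.54 ± 0.22 in rescued and 5.51 ± 0.24 in knockout cells (SD, n = 4 each), a difference of 0.02 with an adjusted p of 0.911. This probe was dim, and was detected on 4 rescued and 3 knockout arrays. The other 2 Atp2b4 probes were not detected on any array. Whether these probes lie within the deleted part of the gene or within the electroporated cDNA was not analysed here, so they do not check the labels. Atp2b1, which encodes the widely expressed pump PMCA1, rose from 8.52 ± 0.10 to 8.79 ± 0.03 (log2 difference 0.27, adjusted p = 0.0131), and centring each chromosome, an alternative chosen after seeing the data, ended this call (0.16, adjusted p = 0.108). Atp2b2 and Atp2b3 were not detected on any array. Of the 2 pump genes measured, 1 rose, and likewise 1 when adjusted over the list alone.

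Rescued and knockout cells differed in a large part of the measured transcriptome. Of 12658 probes tested, 4906 (38.8%) passed the threshold, 2537 higher and 2369 lower in rescued cells. At gene level, 1810 genes were higher and 1635 lower of 8633. Most differences were modest: the median absolute log2 difference of these probes was 0.47, and 674 probes also differed by at least 2-fold, 331 higher and 343 lower. The 2 groups did not overlap at 38.8% of probes, where chance gives 2.86%. Requiring a change of at least 1.5-fold left 1765 probes, and an adjusted p under 0.01 left 3037.

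The replication machinery and the mitotic genes rose together in rescued cells. Whether both groups stood at the same cycle stage at harvest was not tested, so these rises are not shown at a matched stage. Of 44 measured G1/S genes, 42 rose, 0 fell and 2 did not pass, with a median log2 difference of 0.55 (1.46-fold). Mcm6, a subunit of the replicative helicase, rose from 10.14 ± 0.06 to 11.20 ± 0.11 (adjusted p = 8.89e-06), and Mcm2, Mcm10 and the clamp loader subunit Rfc4 rose by 0.90, 0.81 and 0.87 on the log2 scale. A second probe of Rfc4 differed by 0.06. Of 41 measured G2/M genes, 39 rose and 0 fell, with a median of 0.73 (1.66-fold). Cenpa, the centromeric histone, rose from 12.29 ± 0.09 to 13.61 ± 0.18, Cdca3 by 1.29, the kinesin Kif23 by 1.18, and Foxm1, a transcription factor for mitotic genes, by 0.99. Adjusted over the list alone, the counts were again 42 and 39. Relative to all other genes both lists were higher (camera, adjusted p = 1.49e-15 for G1/S and 4.02e-17 for G2/M). With an estimated correlation the call held for G1/S genes (adjusted p = 0.0409) and was lost for G2/M genes (adjusted p = 0.215 with an estimated correlation).

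Among cyclins, CDKs, their inhibitors and E2F factors, 14 of 32 genes rose and 5 fell (16 and 6 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.142, or 0.497 with an estimated correlation; fry called it higher, adjusted p = 0.00627). The CDK inhibitor genes Cdkn2b and Cdkn2a, neighbours at 1 locus, fell by 1.505 and 1.02 on the log2 scale (adjusted p = 3.98e-05 and 0.00167). Skp2, which targets a CDK inhibitor for degradation, rose by 0.37, and Max, the partner of Myc, fell by 0.40; centring each chromosome ended both calls (0.15 and -0.09). Of 24 p53 target genes, 10 rose and 2 fell (11 and 3 adjusted over the list alone). The death receptor Fas rose by 1.67, Rprm by 1.10, and Pmaip1, not detected in knockout cells, by at least 1.96-fold, while the kinase gene Plk3 fell by 1.12. The p53 list did not pass (adjusted p = 0.0671, 0.512 with an estimated correlation), but passed with no detection filter (0.00840) and without rescued replicate 2 (0.0311) or rescued replicate 4 (0.0471); over the other settings of camera with the preset correlation it ran from 0.0510 to 0.132, and fry called the list higher (adjusted p = 0.0169).

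**Figure D1:**
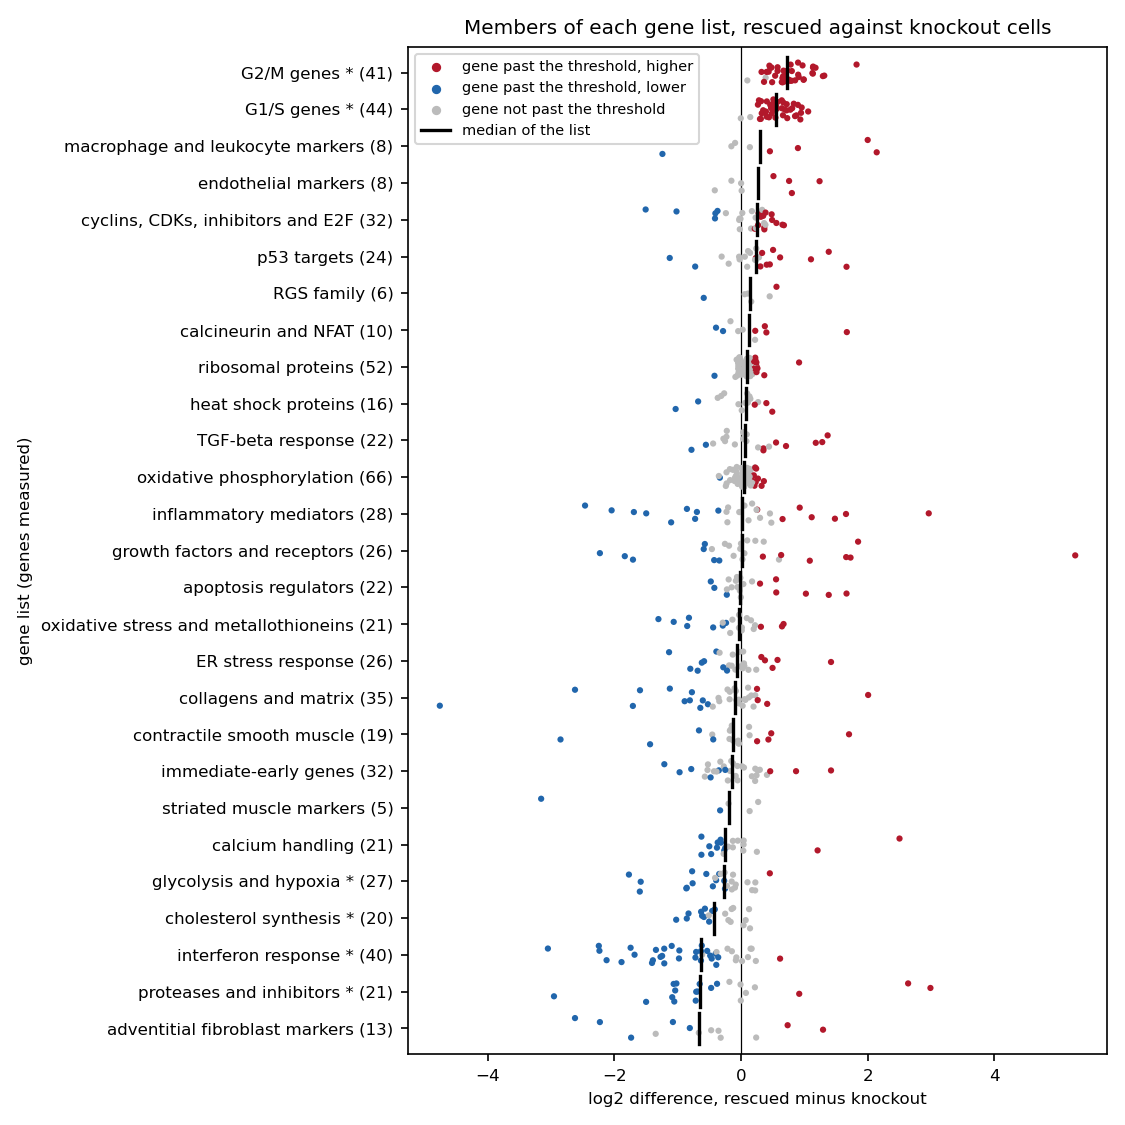
Log2 difference (rescued minus knockout, horizontal axis) of each measured gene in the 27 tested gene lists (rows, with the number of genes measured), with a black bar at each list's median and an asterisk on the 6 lists past the threshold with the preset correlation. Of these 6 lists, G1/S alone passed with an estimated correlation. Nearly all G1/S and G2/M genes lie right of 0, with medians of 0.55 and 0.73, while the interferon response genes lie mostly left of it, with a median of -0.63.

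Col2a1, the collagen of cartilage, was not detected on any knockout array and stood at 10.67 ± 1.31 (SD, n = 4) in rescued cells, at least 41.4-fold higher (adjusted p = 5.20e-05). Igfbp5, an insulin-like growth factor binding protein, rose from 7.55 ± 0.19 to 12.83 ± 0.73 (adjusted p = 2.32e-06), and Sytl2, a vesicle transport gene, rose by 4.69 on the log2 scale, having been detected on 3 knockout arrays. Krt13, Dlk1 and Sprr2d were also undetected in knockout cells and rose by at least 10.6-fold, 6.72-fold and 5.97-fold. The vasopressin receptor gene Avpr1a rose by 3.55, Stard10 by 3.20, the RNA-binding protein gene Igf2bp3 by 3.19, 4930486L24Rik by 3.08, the collagenase gene Mmp13 by 2.99 and Tnfrsf11b, which encodes osteoprotegerin, by 2.96. The 2 other probes of Mmp13 ranged from -0.16 to 1.80. Differences of probes near background depend on its correction: without it all these genes stayed past the threshold, but Col2a1, Sytl2, Krt13, Dlk1 and Sprr2d rose by 3.77, 3.14, 2.15, 1.59 and 1.47 on the log2 scale, those with a bound by less than it.

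In the other direction, the transcription factor gene Tfap2b stood at 10.45 ± 0.03 in knockout cells and was not detected on any rescued array, at least 38.0-fold lower (adjusted p = 2.93e-10). Its relative Tfap2a fell by 3.94, with 3 rescued arrays detected. Thbs2, a matricellular thrombospondin, fell from 11.09 ± 0.11 to 6.34 ± 0.89, and Angpt2, a ligand of the endothelial receptor Tek, from 12.11 ± 0.02 to 8.15 ± 0.15 (adjusted p = 4.60e-09). Ptx3, Evi2a and Tac1, the last encoding the precursor of substance P, were undetected in rescued cells and at least 8.34-fold, 7.81-fold and 7.06-fold lower. The protocadherin gene Pcdh17 fell by 4.63 and Eps8l2 by 4.41, each detected on 1 rescued array. Without background correction these genes also stayed past the threshold, with smaller differences for Tfap2b (-3.58), Pcdh17 (-2.88), Eps8l2 (-2.71), Tfap2a (-2.49), Ptx3 (-1.93), Evi2a (-1.70) and Tac1 (-1.64), under the bounds where one is given, and a second Evi2a probe differed by -1.09. AA467197 fell by 4.10, the guidance factor gene Slit2 fell by 3.55, and Akr1c18, which inactivates progesterone, fell by 3.86.

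**Figure D2:**
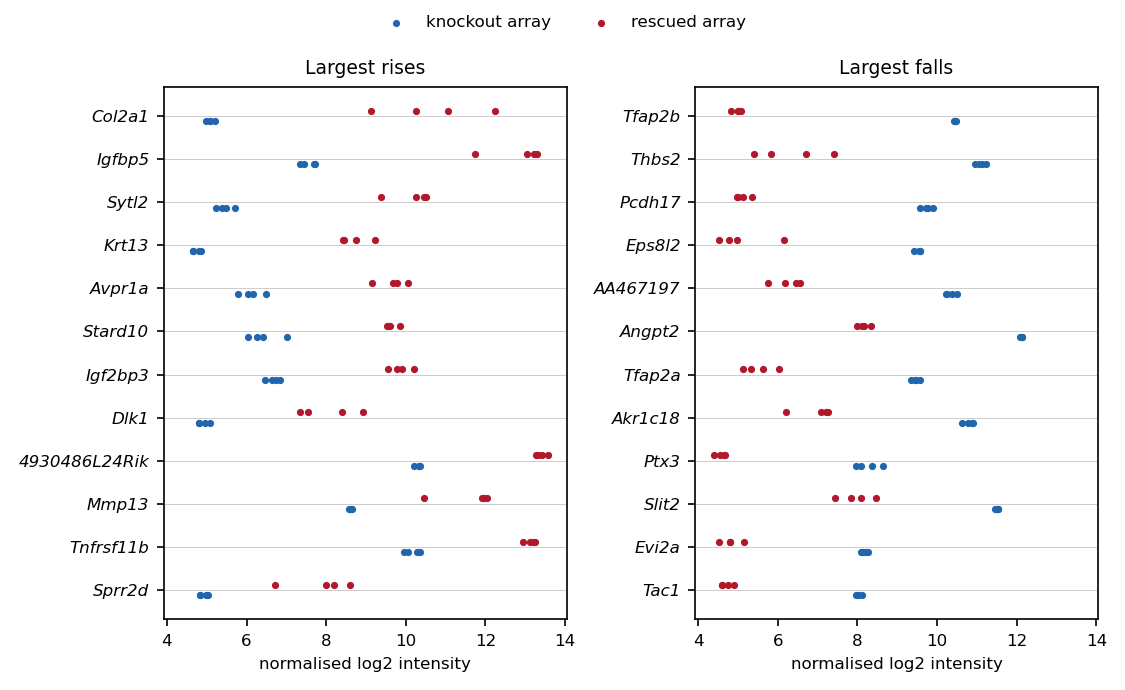
Normalised log2 intensity (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall, 1 point per array, with 4 rescued (red) and 4 knockout (blue) arrays per gene. The groups do not overlap at any of these genes because the rule that chose them requires it. Col2a1 spreads widest among rescued arrays (SD 1.31), while its knockout arrays lie at 5.09 ± 0.09, not detected.

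Interferon-stimulated genes were lower in rescued cells. Of 40 measured, 28 fell, 1 rose and 11 did not pass (30 and 2 adjusted over the list alone), with a median of -0.63. The ubiquitin-like modifier gene Isg15 fell from 10.76 ± 0.42 to 7.71 ± 0.20 (adjusted p = 4.78e-06), the antiviral synthetase gene Oas1g by 2.23, the GTPase gene Gbp2 by 2.12 and Ifi202b by 1.21. The mean of the list fell by 0.83, to 8.17 ± 0.20 on rescued arrays (SD, n = 4; SD of knockout arrays 0.17, n = 4). The list passed relative to other genes (adjusted p = 4.00e-08, but adjusted p = 0.497 with an estimated correlation).

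Of 27 genes of glycolysis and the hypoxia response, 13 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.26. Adm, which encodes the vasodilator adrenomedullin, fell by 1.58, the aldolase gene Aldoc by 1.77, the prolyl hydroxylase gene Egln3 fell by 1.597 and the phosphofructokinase gene Pfkl by 0.86. Of 20 cholesterol synthesis genes, 10 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.43. Fdps, which makes farnesyl diphosphate, fell from 13.10 ± 0.05 to 12.27 ± 0.09, Hsd17b7 by 1.02, Mvd by 0.86 and Hmgcs1 by 0.61. Both lists passed relative to other genes (adjusted p = 0.000419 and 0.000457), and neither did with an estimated correlation (adjusted p = 0.0556 and 0.215).

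**Figure D3:**
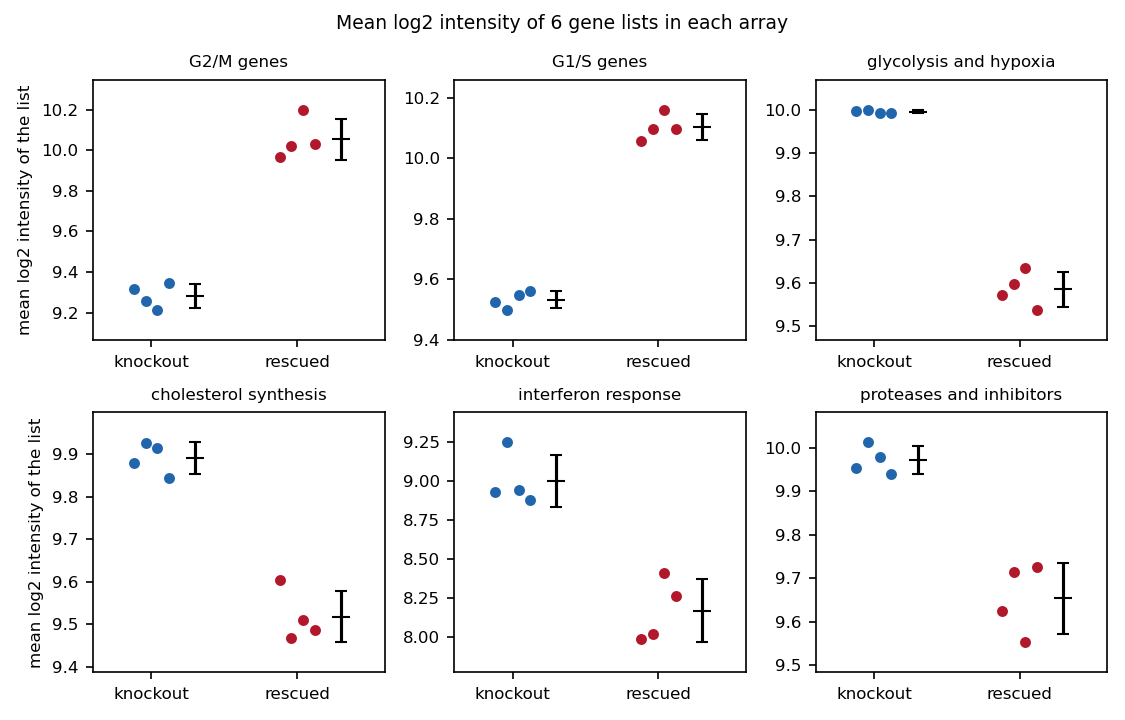
Mean normalised log2 intensity of the 6 gene lists past the threshold with the preset correlation, of which G1/S alone passed with an estimated one (vertical axes, which do not start at 0), 1 point per array, with the mean and SD of 4 arrays beside each group. Rescued arrays lie above all knockout arrays for G1/S genes (10.10 ± 0.04 against 9.53 ± 0.03) and below them for glycolysis and hypoxia genes (9.59 ± 0.04 against 9.995 ± 0.0035).

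Genes of matrix turnover moved both ways. Of 21 proteases and inhibitors, 13 fell and 3 rose, with the same counts adjusted over the list alone and a median of -0.65. The metalloproteinase gene Mmp23 fell by 2.95 and Adamts1 by 1.09, whereas Mmp3, which encodes stromelysin, rose from 8.85 ± 0.14 to 11.49 ± 0.24 (adjusted p = 5.73e-07), as did Mmp13. The list passed as lower (adjusted p = 0.00706, but adjusted p = 0.121 with an estimated correlation). Of 35 collagen and matrix genes, 11 fell and 4 rose (12 and 4 adjusted over the list alone). Thbs2 led the falls, Loxl1, an elastin cross-linking enzyme, fell by 1.59 and the microfibril gene Mfap5 by 2.62, and Tnxb, which encodes tenascin X, rose by 2.01. This list did not pass (adjusted p = 0.09999, 0.523 with an estimated correlation; fry called it lower, adjusted p = 0.0485); without rescued replicate 3 (adjusted p = 0.00669) and with array weights (0.0244) it did.

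Of 19 contractile smooth muscle genes, 4 rose and 4 fell (4 and 5 adjusted over the list alone). The list did not pass relative to other genes (adjusted p = 0.392, 0.527 with an estimated correlation), while fry, which makes no such comparison, called it lower (adjusted p = 0.0140). Actg2, smooth muscle gamma actin, fell from 8.73 ± 0.25 to 5.88 ± 0.33 and Tagln by 1.43, while Myocd, a coactivator of contractile genes, rose by 1.70 after being detected on 1 knockout array. Without background correction Actg2 and Myocd stayed past the threshold but differed by only -1.74 and 0.70. Tpm2 fell by 0.66 at the probe used, but another of its probes differed by 0.92, and the average of both by 0.13 (adjusted p = 0.571). Acta2, a list member named because its signal reached 61411, stood at 15.83 in rescued and 15.87 in knockout cells, where a difference would be compressed.

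Among calcium handling genes 2 of 21 rose and 10 fell (2 and 11 adjusted over the list alone), and the list did not pass relative to other genes (adjusted p = 0.0671, 0.363 with an estimated correlation; fry called it lower, adjusted p = 0.00147). Atp2a3, an endoplasmic reticulum calcium pump, rose from 6.02 ± 0.10 to 8.52 ± 0.46 (adjusted p = 1.72e-05) and the calmodulin kinase gene Camk2b rose by 1.21. Camk2g and Orai1, the pore of store-operated calcium entry, fell by 0.62 each, and a second Camk2g probe differed by -0.10. Of 10 calcineurin and NFAT genes, 4 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.457, 0.523 with an estimated correlation; fry called it higher, adjusted p = 0.000804). Nfatc1, which calcineurin activates, rose by 1.67, Rcan1, a calcineurin regulator, by 0.40 and Nfatc3 by 0.38, while Rcan3 fell by 0.39; centring each chromosome ended the call of Rcan3 (-0.20, adjusted p = 0.0704). In the RGS family, regulators of G protein signalling, 1 of 6 genes rose (Rgs10, 0.56) and 1 fell (Rgs3, -0.59), also adjusted over the list alone (list adjusted p = 0.762, 0.788 with an estimated correlation). Rgs17 and Rgs12 differed by 0.45 and 0.06 without passing, and Rgs17 passed without rescued replicate 3 (0.71, adjusted p = 0.0298). Rgs16, which the study chose on these samples, so that it is not independent evidence, stood at 9.23 ± 0.79 in rescued and 9.07 ± 0.12 in knockout cells (log2 difference 0.16, adjusted p = 0.728). Its value on rescued replicate 3 was 8.09; without that array the difference was 0.54 (adjusted p = 0.00952).

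Growth factor and receptor genes split evenly, with 7 of 26 higher and 7 lower (8 and 7 adjusted over the list alone; list adjusted p = 0.838, 0.834 with an estimated correlation, while fry called the list higher, adjusted p = 0.00627). The receptor gene Egfr rose from 9.82 ± 0.10 to 11.48 ± 0.12, Igf1 by 1.85 and Pdgfc by 1.73, beside Igfbp5. Pdgfra, a receptor for PDGF, fell by 2.23. Of 28 inflammatory mediators, 7 rose and 9 fell (8 and 9 adjusted over the list alone; list adjusted p = 0.762, 0.802 with an estimated correlation). Ptges, a prostaglandin E synthase, fell by 2.46, the cytokine gene Csf1 by 1.69 and Tnfaip2 fell by 1.496, against the rise of Tnfrsf11b; the list's median (0.02) and mean (-0.04) differed in sign.

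Marker lists of other cell types did not pass relative to other genes in camera, though adventitial markers had an unadjusted p under 0.05 and fry called the endothelial, macrophage and striated muscle lists. Single markers passed, as did 3445 of all 8633 genes. Of 13 adventitial fibroblast markers, which hold Pdgfra and Mfap5, 5 fell and 2 rose (6 and 2 adjusted over the list alone); the actin-severing protein gene Gsn fell by 1.73 and Pcolce2 rose by 0.74. The list did not pass (adjusted p = 0.0860, 0.512 with an estimated correlation), and did without rescued replicate 3 (adjusted p = 0.00257), with array weights (0.0161) and with no detection filter (0.0223). Of 8 macrophage and leukocyte markers kept, out of 23 on the array, 4 rose and 1 fell, also adjusted over the list alone. The list did not pass (adjusted p = 0.142, 0.512 with an estimated correlation). Lysozyme genes Lyz1 and Lyz2 rose by 2.00 and 2.14, Lyz2 having been detected on 1 knockout array, and Cd14 by 0.90, while Cd53 fell by 1.24. Lyz2 and Cd53 differed by only 0.96 and -0.54 without background correction, both still past the threshold. Of 8 endothelial markers kept, out of 19 on the array, 4 rose and 0 fell (4 and 1 adjusted over the list alone). The list did not pass (adjusted p = 0.369, 0.512 with an estimated correlation). Plvap and Flt1 rose by 0.76 and 0.80, and Vwf and Nos3, both undetected in knockout cells, by at least 1.53-fold and 1.25-fold. Vwf and Nos3, and Col2a1 among the cartilage and bone markers below, were kept through the rescued arrays alone, so they could count only as rises. Of 4 cartilage and bone markers kept, out of 12 on the array and too few for a list test, 3 rose, also adjusted over the list alone. These were Col2a1, Bglap, which encodes osteocalcin (1.57), and Alpl (0.71), whose call was lost with no detection filter and without any 1 of 5 arrays (rescued replicates 1 and 3, knockout replicates 1, 2 and 3; adjusted p from 0.0572 to 0.0885); Sox9 differed by 0.16 without passing.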

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

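Both tests of rescued replicate 3 were chosen after its values were seen. Among 340 groups of 4 arrays, over the named genes, the list means and the array measures, 20 had 1 array whose gap to its nearest neighbour exceeded, as a share of the group's range, Dixon's 95% critical value for 4 samples, where chance flags about 1 in 20. Of these, 5 concern rescued replicate 3. On that array Mmp13 stood at 10.46 (other rescued arrays 11.93 to 12.04), Akr1c18 at 6.20 (7.08 to 7.25), Cenpa at 13.87 (13.50 to 13.54), Tnfaip2 at 10.22 (9.75 to 9.83) and Ndufa4 at 14.21 (14.12 to 14.13). Igfbp5 was 11.75 on rescued replicate 2 (13.04 to 13.29), Hmox1 9.69 on rescued replicate 1 (10.16 to 10.25) and Mmp23 6.63 on rescued replicate 4 (5.68 to 5.74).

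On knockout arrays, Isg15 was 11.39 on replicate 2 (others 10.51 to 10.61), as was the interferon list's mean, 9.25 (8.88 to 8.94). Replicate 2 also stood apart for Eps8l2, 9.41 (9.55 to 9.57), and for the mean of the ribosomal protein list, 13.81 (13.85 to 13.85). Replicate 1 stood apart for Egln3, 7.31 (7.60 to 7.65), and for the calcium handling mean, 10.04 (9.991 to 9.996). On replicate 3, 4930486L24Rik was 10.22 (10.33 to 10.35), Plvap 7.05 (7.37 to 7.40), Lep 5.97 (5.60 to 5.62) and the p53 target mean 10.12 (10.13 to 10.14). On replicate 4, Tnxb was 7.37 (7.57 to 7.61) and the immediate-early mean 9.52 (9.65 to 9.66).

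Rescued replicate 3 lay apart from the other rescued arrays on the second principal component, which held 10.965% of the variance, and 159 genes differed from the mean of the other rescued arrays by 2-fold or more. A larger share of unrescued cells on that array, as the only cause, would place these genes between the other rescued and the knockout arrays. Of them, 113 (71.1%) lay outside that span by more than 0.25. Because the genes were selected for their distance from the other rescued arrays, a contribution of unrescued cells stays open. The list of adventitial fibroblast markers, all 13 of which were detected on every knockout array and 3 of which stand in another list, had a median shift of 1.13 on this array, at percentile 100 of random lists matched on expression. Its members brightest on this array, Dcn and Dpt, chosen after their values were seen, stood at 13.35 and 12.05 against means of 10.66 and 9.61. Of the 13 members 11 were higher on this array, while Mfap5 and Pcolce2 were lower by 1.06 and 0.31. G2/M, p53 target, matrix and interferon genes were also at percentile 100. At the other end, contractile smooth muscle and immediate-early genes were at percentiles 0.16 and 0.74. More cells of this type may account for part of the pattern, as a hypothesis, but the test does not single out this cell type, since other lists also reached percentile 100. A change within the smooth muscle cells of that culture was not tested.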

How the results depend on the processing

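Centring each chromosome was chosen after seeing the data; the other alternatives were chosen before. Other background corrections, normalizations, detection filters, variance models and array weights left from 4345 to 5240 probes past the threshold, and the average of a gene's probes 3817 genes. With each array left out in turn the count was 4141 to 5056 (2125 to 2594 higher, 2016 to 2462 lower), and 6 to 8 lists passed. The replicate number as a block gave 4206 probes, of which 4099 were among those called without it. Deviations from the group mean did not match between arrays of the same number (correlations -0.081 to -0.0030). No pairing by number was seen, but these few correlations do not exclude one. An adjusted p under 0.01 left 3037 probes (1559 higher, 1478 lower) and a change of at least 1.5-fold 1765 (887 higher, 878 lower), as stricter thresholds must. Of the lists, 1 passed with an estimated correlation and 22 with fry, which asks a different question. With no detection filter 9 lists passed, the 6 and the p53 target, adventitial and ribosomal lists.

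Of 126 named genes past the threshold, 35 differed by over 1.5 times less without background correction and 21 with normexp and an offset of 50; each lost 1 call, of Myog. None of the bounds given for the 12 named genes undetected in 1 group holds without the correction; beside those in the report, Pmaip1, Atf3, Vwf and Nos3 differed by 0.52, 0.53, 0.48 and 0.18. The sign of Atp2b4 turned with array weights (-0.018) and chromosome centring (-0.061), and ran from -0.042 to 0.13 with an array left out; the probe has no value under the strict detection filter. Of 2762 values for 140 other genes, 2710 kept direction and side of the threshold, 30 lost the call, 13 gained one and 9 changed sign. This count overstates stability. Detection filters, the other variance model and the replicate block cannot change the log2 difference of a probe, and the deposited log2 values were nearly those used here. Most of these genes were also chosen by small p or large difference in these data. Signs turned for Pmp22 and Pnpla2 with array weights (-0.028 and 0.0014) and for Tpm2 with averaged probes (0.13), whose probes disagree. With an array left out, Pmp22 ran from -0.072 to 0.18, Pnpla2 from -0.20 to 0.036, Rgs16 from -0.042 to 0.54 and Tubb3 from -0.091 to 0.22. Of 563 values for 27 lists, 543 kept direction and side, 5 lost the call, all with an estimated correlation, 9 gained one and 6 changed the direction that camera, which ranks a list against other genes, gives. These 6, with their mean differences, which changed sign for inflammatory mediators, oxidative phosphorylation and ribosomal proteins alone, were growth factors (0.17) and inflammatory mediators (0.27) under strict detection, heat shock proteins (-0.091), oxidative phosphorylation (-0.035) and ribosomal proteins (-0.012) with median scaling, and the RGS family without a filter (0.031). Other than for Tpm2 and the thresholds, the cause was not tested. A block for the slide was not run, since no slide is given. Probes near background limit small differences: Atp2b4 had a signal of at most 136.5 against array medians of 108.0 to 118.2.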

Other observations

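The test of the Atp2b4 probes and the comparison of chromosomes between single arrays were chosen after the result was seen. Further gene groups fixed in advance held single changes past the threshold, while the lists did not pass relative to other genes. Of those tested in this part, fry called all but the immediate-early and heat shock lists, with adjusted p of 0.00193 for TGF-beta, 0.00555 for apoptosis, 0.00257 for ER stress, 0.00193 for oxidative stress, 0.00627 for oxidative phosphorylation, 0.00183 for ribosomal proteins and 0.0274 for striated muscle. In the TGF-beta response 7 of 22 genes rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.341, 0.512 with an estimated correlation): Tgfbi rose by 1.28, the BMP antagonist gene Grem1 by 1.37, Ltbp4 by 1.18 and Skil by 0.55. Among apoptosis regulators 6 of 22 rose and 3 fell (6 and 4 adjusted over the list alone; list adjusted p = 0.565, 0.740 with an estimated correlation; median -0.02, mean 0.17), with Traf2 up by 1.02 and Bcl2 by 0.55 beside Fas and Pmaip1. Of 32 immediate-early genes, 3 rose and 6 fell, also adjusted over the list alone (list adjusted p = 0.330, 0.583 with an estimated correlation). Errfi1, an inhibitor of the EGF receptor, fell by 0.97, the shear-responsive factor gene Klf2 by 1.21 and Zfp36 by 0.48, while Atf3, undetected in knockout cells, rose by at least 1.96-fold.

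In the ER stress list 5 of 26 genes rose and 8 fell, also adjusted over the list alone (list adjusted p = 0.392, 0.512 with an estimated correlation): the chaperone genes Dnajb9 and Calr fell by 1.14 and 0.62, and Atf4 rose by 0.58. Of 21 genes of oxidative stress and metallothioneins, 3 rose and 7 fell (3 and 8 adjusted over the list alone; list adjusted p = 0.341, 0.512 with an estimated correlation). Heme oxygenase Hmox1 fell by 1.30, Nqo1 by 0.85, Mt2 by 0.82 and Gpx3, detected on 1 rescued array, by 1.06 (-0.39 without background correction). Of 16 heat shock proteins, 3 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.838, 0.834 with an estimated correlation; median 0.08, mean -0.05). Hspa1a fell by 1.03 and Hspb1 by 0.68, and Hspb8 and Hsph1 rose by 0.40 and 0.49. For 66 genes of oxidative phosphorylation (9 rose, 1 fell; 2 and 1 adjusted over the list alone) and 52 ribosomal protein genes (10 rose, 1 fell; 4 and 1 adjusted over the list alone) the adjusted p was 0.341 and 0.0845 (0.512 and 0.497 with an estimated correlation), and both means turned negative with median scaling (-0.03 and -0.01); the ribosomal list passed with no detection filter (adjusted p = 0.0228). Ndufa4, Ndufa6 and Cox7c rose by 0.36, 0.32 and 0.24 and Ndufc1 fell by 0.33. Rps15a, Rpl13a and Rps15 rose by 0.92, 0.37 and 0.24 and Rpl22 fell by 0.42. Median scaling ended the calls of Ndufa4, Cox7c and Rps15, centring each chromosome those of Ndufa6 and Rps15, and leaving out knockout replicate 1 or blocking on the replicate number that of Cox7c (adjusted p = 0.0531 and 0.0623).

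Among the remaining cell type lists, the adipocyte genes Pparg and Lpl rose by 1.82 and 1.59 (2 of 4 measured, also adjusted over the list alone), while Lep and Pnpla2 differed by -0.32 and -0.08, and Lep passed without rescued replicate 1 (-0.43, adjusted p = 0.0358). Of 4 epithelial and mesothelial genes, Krt19 rose by 2.62, having been detected on 1 knockout array, and 0 fell (1 and 1 adjusted over the list alone). Without background correction Krt19 differed by 1.265, still past the threshold. Upk3b, Cdh1 and Cldn7 differed by -0.32, 0.25 and 0.15, and without rescued replicate 3 Upk3b and Cdh1 passed (adjusted p = 0.00581 and 0.0373), Upk3b in 4 of 20 alternatives. Of 5 striated muscle genes 0 rose and 2 fell (0 and 3 adjusted over the list alone; list adjusted p = 0.369, 0.512 with an estimated correlation). Acta1 fell by 3.15, detected on 3 rescued arrays, and Myog by 0.33, a call lost in 13 of 19 alternatives (adjusted p from 0.0513 to 0.131), among them leaving out any 1 array other than knockout replicate 1, and no background correction, where the difference was -0.11. Tnnc1, which passed in 5 of 20 alternatives, and Myl2 differed by -0.20 and 0.27. None of the 3 neural genes passed in limma, and 0 passed adjusted over the list alone (Ngfr -0.08, Pmp22 0.08, Tubb3 0.07).

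The number of probes past the threshold is high for 4 arrays against 4. Of the 35 splits of these 8 arrays into 4 and 4, only the real one gave as many as 4906 probes. The highest of the others gave 0, so a chance split is unlikely, though 1 of 35 is the smallest share possible. Every other split mixes the groups and places their difference in the spread, so its count of 0 is no separate evidence. As the labels do not say whether replicates are separate cultures, the splits do not measure differences between cultures. No single array carried the count, the lowest with 1 array left out being 4141. Whole chromosomes shifted: the 281 genes of chromosome 12 had a median 0.32 below all autosomal genes (difference -0.319), 138 of them past the threshold lower and 12 higher, with chromosome 4 at -0.20 and chromosome 15 at 0.19, and 9 autosomes lay outside the range of random gene sets. For chromosomes 4, 12 and 15 the exact permutation p between the groups of arrays was 0.0286, the smallest possible, or 0.0571 after adjustment over 20 chromosomes. Chromosomes 1, 3, 5, 6, 10, 18 and 19 had the same p, so it does not single out those named. Chromosomes 5 and 18 lay within the range of random gene sets, while chromosome 3 stood at -0.16. A gain or loss of chromosomes in 1 of the cultured populations may account for part of the differences, as a hypothesis, since DNA was not analysed here. After each chromosome was centred 4564 probes passed, among them 4068 of the 4906 called without centring. A uniform shift of whole chromosomes therefore does not account for most calls. Centring does not remove shifts of parts of chromosomes or effects on genes of other chromosomes, so how far these contribute stays open. An effect of PMCA4a, of electroporation or of separate culture stays open, because each of these differs with the group.

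The shifts also varied within the rescued group. Chromosome 12 genes lay at a median of -0.30 relative to the mean of all arrays on rescued replicate 1, and between -0.12 and -0.09 on the other rescued arrays, against 0.15 to 0.17 on the knockout arrays. On rescued replicate 3, genes of chromosome 17 were lower than in the other rescued arrays by 0.15 more than autosomal genes in general (-0.151). On rescued replicate 4 the same comparison gave -0.112 for chromosome 1. Such shifts argue against the rescued arrays being repeats of 1 RNA sample. For the knockout arrays the question stays open. A difference in sex between the populations would set Xist or the brightest Y-linked gene measured, Eif2s3y, apart by over 2 on the log2 scale. Eif2s3y stood at 9.31 ± 0.27 in rescued and 9.56 ± 0.13 in knockout cells, and the Xist probes differed by -0.08 and 0.05. The Y-linked genes Kdm5d and Uty lay too near background for a fall of that size, and differed by -0.266 and 0.20. Hoxd4 and Hoxd8, chosen after their values were seen, were undetected in rescued cells and at least 3.66-fold and 2.86-fold lower. They were 2 of 14 measured Hox genes with a 2-fold change, against 518 of all 8633 genes (Fisher exact p = 0.204), so whether the populations differ in positional origin cannot be told apart from a general change, given the few Hox genes measured.

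Atp2b4 did not rise in cells that received its cDNA, with a difference of 0.0247. Probes outside the electroporated sequence may give this value, and so may low or lost expression; the 2 cannot be told apart because neither the probe nor the cDNA sequence was used here.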
